A study of Zea mays with 56 samples.

How the data were processed

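Leaves of 28 maize plants of the inbred W22 were profiled, each plant with an RNA-seq and a small RNA-seq library, which gave 56 samples. The plants carried 0 to 7 B chromosomes. B chromosomes are extra chromosomes that a maize plant does not need and that come in addition to its regular set, the A chromosomes. Per the labels, copy number was typed in seedlings by fluorescence in situ hybridization, the plants were 45 days old and greenhouse grown, and total RNA was isolated with a kit that keeps small RNAs. There were 4 control plants without B chromosomes, 4 plants each with 1, 2, 3 and 4 copies, 2 with 5, 3 with 6 and 3 with 7; these groups are written 1B to 7B. The labels call the plants of a group biological replicates.

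The authors deposited 4 tables of measurements that were tested here. Transposable elements (TEs), 92 ERCC spike-in RNAs (synthetic RNAs added to each RNA sample in known amounts) and 98 miRNA loci were deposited as raw read counts. The deposited gene table holds FPKM values for 41064 genes, found from its values: they are not whole numbers and low values of a gene step by single reads. The authors had scaled these FPKM values between libraries, since the median ratio of a gene to its geometric mean lay between 1.009 and 1.013 in every library. The labels do not name the assay of the TE table, which was taken as RNA-seq. The authors also deposited the TE values as RPKM, with TMM-scaled totals as the values show, and the miRNA values as RPM of each small RNA library; the RPM gave the small RNA depth, and no test used either. Their own comparisons of each copy number with control were deposited with log2 fold changes and p-values, from Cuffdiff for genes and an edgeR likelihood-ratio test for TEs and miRNAs, per the file headers. Per the submitters' processing notes, cutadapt 1.16, TopHat2, Bowtie2, edgeR and Cuffdiff were used, with no role stated. The genome build, the annotation and the treatment of reads that map to several places were not given in the sources used here. Coordinates are those of the authors' deposited tables.

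The tests had been planned for gene counts. Because the gene table held FPKM, genes were instead tested with limma 3.58.1 (moderated test with a mean-variance trend) on log2(FPKM + 0.5), without further scaling, over genes at 0.5 FPKM or more in at least 2 libraries. Gene fold changes are therefore on the log2(FPKM + 0.5) scale, which understates changes of low genes. TE and miRNA counts were tested with the quasi-likelihood test of edgeR 4.0.16 with TMM factors after filterByExpr by group, in R 4.3.3. The standard error of an edgeR log2 fold change was taken as its size divided by the square root of the F statistic. All 28 libraries of an assay entered 1 fit with 8 copy-number groups. B presence was the mean of the 7 carrier groups minus control, with each group weighted equally, and each copy number was also set against control; these comparisons share the same 4 control plants. B dosage was the slope per B copy among the 24 carriers, with the controls left out. Adjusted p-values are Benjamini-Hochberg values over the features tested, with a threshold of 0.05. Features past it are called higher or lower.

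Gene identifiers starting with Zm00044a were taken as B-annotated, since 686 of the 758 lie on the sequence named for the B chromosome and 72 on scaffolds; all other genes are called A-chromosome genes. TEs with zmB in the identifier are called B-tagged. B-specific genes were defined after the files were seen as B-annotated genes under 0.1 FPKM in the control mean and at 1 FPKM or more in the carrier mean. The first 3 letters of a TE identifier were read as the usual superfamily code. The files pair gene identifiers with no names, and 0 of the 41064 identifiers matched the RefSeq gene table (assembly Zm-B73-REFERENCE-NAM-5.0). The gene lists and cell type markers fixed beforehand (photosystem, C4 enzymes and others) were therefore not run. Identifiers are printed for at most 2 features that rose and 2 that fell per comparison, ranked by fold change or slope among called features with the same direction in every copy number and a mean of at least 1 FPKM or 1 CPM (TMM-scaled edgeR counts per library); the FPKM minimum stood in for the planned count minimum.

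The miRNA table names no families. A hand-made list of known mature plant miRNA sequences, written after the files were seen, was matched to the major RNA of each locus with an ungapped overlap of at least 18 nt, at most 2 mismatches and a shift of at most 3 nt. It named 48 of the 98 loci, 37 with an exact match, and 46 of the 71 loci tested. The miRNA family lists themselves (copper, phosphate, sulfate, nitrogen, auxin, leaf development, phase change and silencing feedback) were fixed beforehand. Loci of a family with identical sequences share reads and are not independent.

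Totals per library ranged from 427551 to 1634328 counts for spike-ins, from 738507 to 1623250 for TEs and from 17487 to 120136 for miRNAs. Small RNA depth ranged from 204339 to 1070937 reads. Gene read totals are not part of the FPKM table, so the relative depth of each library was recovered from the single-read steps of genes under 0.3 FPKM: in each library 22.3% to 26.7% of the log2 ratios to a reference library fell in 1 bin of 0.004. Relative gene depth ranged from 0.672 to 1.286, a 1.91-fold range. Floors for features with no reads were set at 3 counts over the group and cover counting error only.

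Gene reads were taken as the FPKM sum of a library times its relative depth, since read totals were lacking. This is a sum of reads per gene length, so a shift between short and long genes also moves it. Gene reads per ERCC read and TE reads per gene read were compared on the log2 scale with exact permutation tests over all 20475 ways to pick 4 control plants (two-sided), and with copy number by Pearson's r and Spearman's rho with 100000 resamples. The share of called A-chromosome genes was tested in windows of 10 Mb with at least 10 tested genes by Fisher's exact test. The TE superfamily shares were added after the files were seen.

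The tests were tried on simulated tables with the real mean levels and depths, but with 1 fixed spread for all features. The rates need not hold for the real data, which gave far more calls and had no fixed spread. With 200 changed genes, limma recovered 16.4% of genes changed 1.5-fold, 82.1% changed 2-fold and 100% changed 4-fold for B presence over 23303 genes. For 1B against control it recovered 2.99%, 37.3% and 98.5%. A slope of 1.2-fold per copy was recovered for 97.0% of genes, for 86.0% of TEs and for 12 of 12 miRNAs. That slope was steeper than any fall called in A-chromosome genes (lowest -0.19 log2 per copy). For TEs and B presence, 74.6% of 2-fold changes were recovered over 4792 TEs. Unchanged features made up 5.04% of the calls for genes and 6.40% for TEs in the presence simulations. The depth recovery was off by at most 2.2e-07 on the log2 scale, and 2 of 2 planted windows were found with 0 others.

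No replicate pair was a duplicate: over 37 pairs within groups, the chi-square per degree of freedom was at least 2.43 for spike-ins, 5.40 for miRNAs and 4.12 for TEs. Alternatives planned before the data were examined were other scalings (relative log expression, spike-in totals, gene library totals, totals without TMM), DESeq2 1.42.0 for counts, no filter on low values, the replicate number as a block, only the groups compared, all 28 libraries for dosage, carriers as a single group, other windows and thresholds, and each library left out in turn. Pseudocounts of 0.1 and 1, a filter at 1 FPKM, quantile normalization and TMM factors on FPKM, another limit for B-specific genes, other reference libraries for TMM (by default 3B replicate 2, a choice that changed when single libraries were left out), and leaving out 3 libraries with an unusual TE composition were added after the data were seen.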

Results

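The study set leaves of W22 maize plants with 1 to 7 B chromosomes against leaves of plants without them. It asked how B chromosomes relate to the expression of genes, transposable elements and small RNAs. The 28 plants comprised 4 controls, 4 each of 1B, 2B, 3B and 4B, 2 of 5B, 3 of 6B and 3 of 7B. Between 20483 and 21144 genes were detected at 0.5 FPKM or more per plant. Library totals ranged from 738507 to 1623250 TE counts, from 427551 to 1634328 spike-in counts and from 17487 to 120136 miRNA counts. The shallowest miRNA library was 3B replicate 1.

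Control plants stood apart from carriers of any copy number in the expression of A-chromosome genes. The first principal component of these genes, with 29.4% of the variance, placed the 4 controls between -102.6 and -88.2 and the 24 carriers between 1.73 and 28.1. The 1B plants lay at 1.73 to 19.1 and the 7B plants at 14.8 to 21.7. The second component held 7.24% of the variance.

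**Figure D1:**
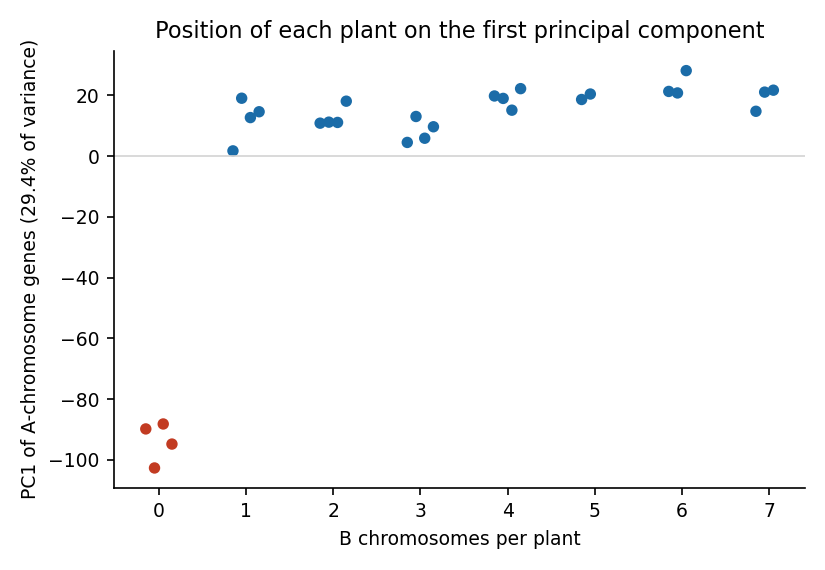
Position of each plant (1 point each, red for controls and blue for carriers) on the first principal component of log2 A-chromosome gene levels, against the number of B chromosomes per plant. The 4 controls lie between -102.6 and -88.2 and all 24 carriers lie above 0.

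For B presence, 11302 of 24159 tested A-chromosome genes were called with limma, 5508 higher and 5794 lower in carriers. The median size of change among them was 0.64 on the log2 scale, and 2738 changed by more than 1. The gene Zm00004b020638 on chromosome 4 (23526708 to 23527696) was listed at 0 in all 4 controls and reached 45.0 ± 12.8 FPKM (SD, n = 24) in carriers, with group means of 45.2 FPKM in 1B and 48.6 FPKM in 7B. The gene Zm00004b007830 on chromosome 2 (87382567 to 87385271) went the other way, from 14.02 ± 4.24 FPKM (SD, n = 4) in controls to 0 in every carrier. Zm00004b020593 on chromosome 4 fell from 25.97 ± 5.77 FPKM in controls (n = 4) to 0.473 ± 0.251 FPKM in carriers (n = 24), a log2 change of -4.81 ± 0.21 (SE; limma adjusted p = 1.1e-15). With scaling by spike-in totals, which raised all genes in carriers by 0.31 on the log2 scale, 6160 genes were higher and 1810 lower, A-chromosome and B-annotated genes together (77.3% higher, against 49.5% of the 11514 such calls without it). The control plants carry another plant code series in the labels than all carriers, and no group holds both.

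Each copy number was also set against the same 4 controls. The number of called genes, A-chromosome and B-annotated together, was 8653 in 1B, 8258 in 2B, 8041 in 3B, 9598 in 4B, 7283 in 5B, 9395 in 6B and 8797 in 7B, with 50.8% to 53.0% of them higher. Over the genes called for B presence, the median change in the called direction was 0.61 in 1B, 0.59 in 2B, 0.58 in 3B, 0.66 in 4B, 0.66 in 5B, 0.70 in 6B and 0.66 in 7B. These genes were chosen on the same controls. With 8584 genes picked against Control replicates 1 and 2 and measured against Control replicates 3 and 4, the medians were 0.65 in 1B, 0.61 in 3B and 0.69 in 7B, and 96.9% (3B) to 98.2% (6B) of the genes kept the direction. The A-chromosome gene with the largest rise in 1B was Zm00004b020638, at 45.2 ± 10.3 FPKM (n = 4). Among named genes that fell in 1B, Zm00004b003081 went from 17.7 ± 7.80 FPKM to 0 (n = 4 each) and Zm00004b018029 on chromosome 3 (165863150 to 165863768) went from 60.2 ± 18.2 to 1.54 ± 0.656 FPKM (n = 4 each; log2 change -4.90 ± 0.34 SE; limma adjusted p = 2.8e-11). In 7B, Zm00004b036731 on chromosome 7 (150726177 to 150728516) stood at 1.19 ± 0.417 FPKM (n = 3) against 51.2 ± 12.02 FPKM in controls (n = 4; limma adjusted p = 1.3e-09). The 5B group has 2 plants, and its count was 4851 without 5B replicate 2. Under spike-in scaling, 64.9% (6B) to 86.9% (4B) of the calls were higher. The authors' deposited table marks 6312 genes in 1B, 6112 in 2B, 5909 in 3B, 7062 in 4B, 5325 in 5B, 6831 in 6B and 6442 in 7B as significant.

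**Figure D2:**
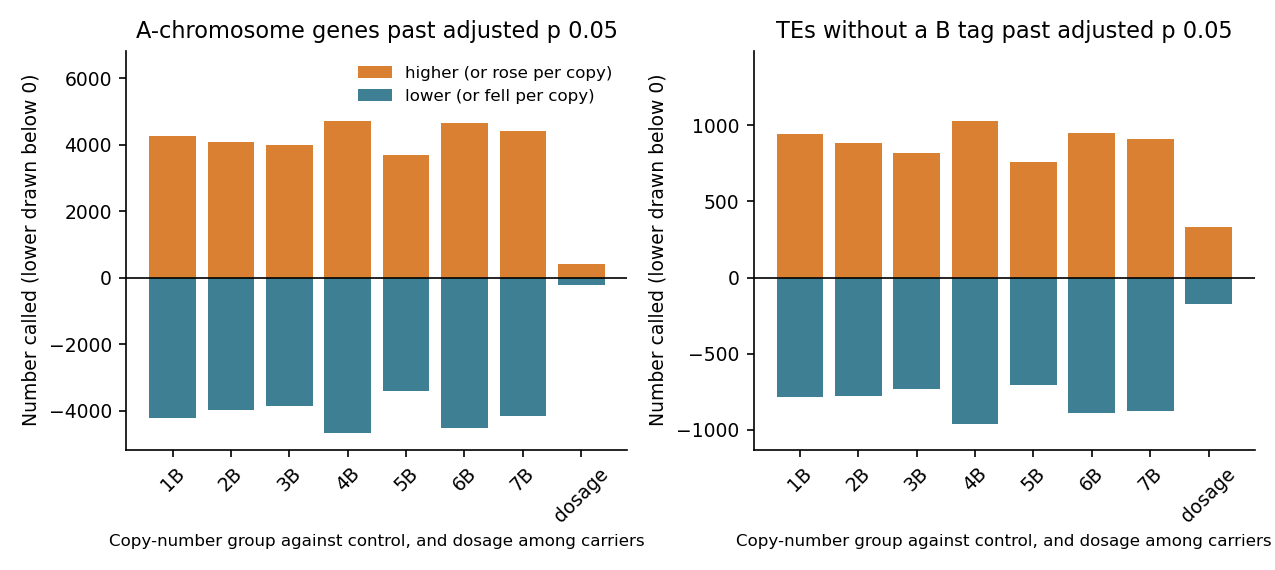
Number of A-chromosome genes (left) and of TEs without a B tag (right) past adjusted p 0.05 for each copy number against control and for the slope per copy among carriers, with higher drawn above 0 and lower below 0. The numbers of calls against control are similar at every copy number (4274 higher and 4240 lower in 1B), while dosage gave 395 that rose and 218 that fell.

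Genes of the B chromosome itself were transcribed in leaves, and most B-specific genes rose with copy number. There were 94 B-specific genes, under 0.1 FPKM in controls by definition. Their summed level was 1.302 ± 0.366 FPKM in controls (SD, n = 4), 217 ± 20.5 in 1B (n = 4), 412 ± 54.2 in 2B (n = 4), 577 ± 26.2 in 3B (n = 4), 820 ± 58.0 in 4B (n = 4), 974 ± 101 in 5B (n = 2), 1078 ± 79.1 in 6B (n = 3) and 1297 ± 52.9 in 7B (n = 3). The gene with the largest presence change, Zm00044a000145 on the B chromosome (21804671 to 21806536), was listed at 0 in controls and rose from 25.8 ± 7.16 FPKM in 1B (n = 4) to 146.5 ± 19.5 in 7B (n = 3). Across the 24 carriers, the sum correlated with copy number with Pearson's r = 0.988 and Spearman's rho = 0.987 (permutation p = 1e-05 each, the smallest that the resamples can give; adjusted p = 2e-05 over 4 relations). Without the 2 plants farthest from the median copy number, r was 0.986. The fitted gain was 178 FPKM per copy, and the sum per copy was 217 FPKM in 1B and 185 FPKM in 7B. Of the 94 genes, 85 rose with dosage by limma and 0 fell. The median ratio of 7B to 1B was 6.33 over the 93 genes with a ratio, with quartiles of 5.17 and 7.84.

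**Figure D3:**
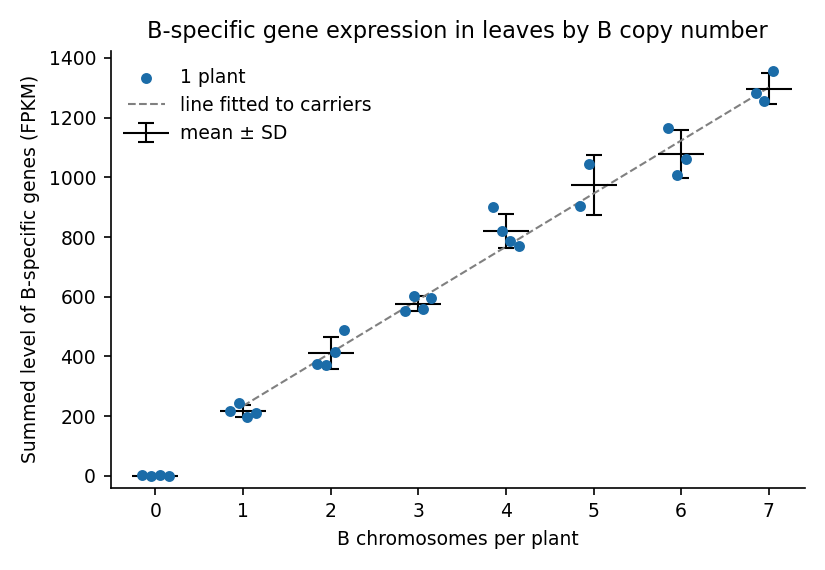
Summed FPKM of the 94 B-specific genes per plant (points) against B chromosomes per plant, with the mean ± SD of each group and the line fitted to the 24 carriers. The sum rises from 217 FPKM in 1B to 1297 FPKM in 7B and is 1.302 FPKM in controls.

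Among all 356 tested B-annotated genes, 189 were higher and 23 lower in carriers by limma. With dosage, 153 of 347 tested B-annotated genes rose (44.1%) and 1 fell, a smaller share than among the B-specific genes, which were selected by their levels. In controls, which have no B chromosome, 92 B-annotated genes had a mean of 1 FPKM or more. Of these 92, 28 were higher and 15 lower in carriers. The gene Zm00044a000500 stayed at 21.5 ± 2.13 FPKM in controls (n = 4) and 21.5 ± 2.57 in 7B (n = 3), while Zm00044a000358 was at 196 ± 17.98 FPKM in controls (n = 4), 41.0 ± 8.43 in 1B (n = 4) and 102 ± 21.99 in 7B (n = 3). Both were chosen after their values were seen. Reads of such genes cannot be assigned to the B chromosome from these tables.

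Among carriers, 613 of 23672 A-chromosome genes changed with B dosage, 395 of which rose and 218 fell per added copy (limma). The gene Zm00004b023323 on chromosome 4 (199588521 to 199589106) was listed at 0 in controls and rose from 0.908 ± 0.663 FPKM in 1B (n = 4) to 18.03 ± 1.32 in 7B (n = 3), a slope of 0.61 ± 0.05 log2 per copy (SE; limma adjusted p = 3.5e-09). Zm00004b007283 on chromosome 2 (44802920 to 44803184) rose from 3.28 ± 1.62 FPKM in 1B to 26.7 ± 15.7 in 7B (slope 0.56 ± 0.09, limma adjusted p = 4.2e-04). Zm00004b030758 on chromosome 6 (153285577 to 153289872) fell from 118 ± 58.0 FPKM in 1B to 61.9 ± 12.7 in 7B (slope -0.19 ± 0.04, limma adjusted p = 0.00366), with 192 ± 59.0 FPKM in controls. Zm00004b026826 on chromosome 8 (137996882 to 138000299) fell from 9.66 ± 2.90 FPKM in 1B to 5.21 ± 0.668 in 7B (slope -0.18, limma adjusted p = 0.0147; with spike-in scaling -0.18 and 0.0612). Of the genes that rose, 67 were under 0.1 FPKM in controls, and 279 were also called higher and 35 lower for B presence. Of the genes that fell, 127 were also called lower for B presence and 23 higher. The median slope of the genes that fell was -0.08 log2 per copy. The total count of genes called for dosage, B-annotated ones included, was 767 (548 rose, 219 fell). It was 457 without 1B replicate 1 (365 rose, 92 fell) and 264 with spike-in scaling (253 rose, 11 fell). The 218 A-chromosome genes that fell had a median slope of -0.08 in both settings. Spike-in scaling moves all slopes nearly alike, by 0.0015 per copy, so their direction could not change. Of the 218 genes, 7 were still called with spike-in scaling and 88 without 1B replicate 1.

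Called A-chromosome genes were spread over all chromosomes. For B presence, 3 of 219 windows of 10 Mb held more called genes than the rest of the genome. They were 170 to 180 Mb of chromosome 7 with 168 of 268 genes (62.7% against 46.6% elsewhere, Fisher's exact adjusted p = 4.1e-05), and 150 to 160 Mb and 160 to 170 Mb of chromosome 3 with 84 of 129 genes (65.1%, adjusted p = 0.00430) and 81 of 127 genes (63.8%, adjusted p = 0.0116). These windows held 2.95% of the called genes, and the median window had 46.3% of its genes called. For dosage, 0 windows passed Fisher's exact test, with 7 at an unadjusted p under 0.05 and a smallest p of 0.0016.

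TEs changed in both directions, and many B-tagged TEs were higher in carriers. For B presence, 2434 of 5359 tested TEs were called by edgeR, 1272 higher and 1162 lower, and 129 of 241 B-tagged TEs were higher and 38 lower. B-tagged TEs were not limited to carriers: they held 6.68% to 9.90% of the TE counts in controls and 3.22% to 8.91% in carriers, and the most abundant of them held 6.11% to 9.12% and 2.79% to 7.76%. The B-tagged Gypsy element RLG00487zmB00001 had 0 counts in controls and 126 CPM over the carriers, at least 189-fold higher against a floor of 0.666 CPM. The B-tagged Helitron DHH00002zmB00367 had 105 CPM over carriers and 0 counts in controls, at least 157-fold higher. Their group means rose from 40.6 ± 16.3 in 1B to 224 ± 19.3 in 7B and from 40.6 ± 1.44 to 182 ± 12.9 CPM (n = 4 and 3). The Helitron DHH00002Zm00004b01751 had 387 counts in the 4 controls and 1 count in the 24 carriers. A second Helitron, DHH00002Zm00004b03266, had 145 counts in controls and 0 in carriers, at least 299.8-fold lower, with an edgeR adjusted p of 1e-09. For it DESeq2 gave a log2 change of -7.70 with an adjusted p of 0.123. With spike-in scaling, 1521 TEs were higher and 604 lower (71.6% higher, against 52.3% here), and with no filter on low counts 4645 TEs were called, 1218 higher and 3427 lower. The element RLG00021Zm00004b00084 took 31.4% of the TE counts in 1B replicate 3, 25.1% in Control replicate 4 and 17.7% in Control replicate 2. Without these 3 libraries, 1781 TEs were called for B presence. The cut was not sharp: the element also took 16.5% in 4B replicate 2, 12.2% in 2B replicate 1 and 11.7% in 4B replicate 3, which were kept.

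TE reads were also summed by superfamily. These sums include B-tagged TEs, and none was made without them. Rises of B-tagged and of other elements can therefore not be told apart in them. By superfamily, L1 LINEs (code RIL) had more reads per gene read in carriers, by 1.29 on the log2 scale (exact permutation adjusted p = 3.2e-04 over 13 superfamilies), and 6 of their 14 tested elements were higher and 0 lower. CACTA elements (DTC) were higher by 0.74 (exact permutation adjusted p = 0.00333) and also rose with copy number (r = 0.785, rho = 0.785, permutation adjusted p = 6.5e-05; r = 0.734 without the 2 farthest plants). Unclassified TIR elements (DTX), with 1 tested element that is B-tagged, were higher by 1.75 (exact permutation adjusted p = 0.00127) and rose with copy number (r = 0.845). They held only 1.5e-04% to 0.0037% of the TE counts of a library, so both values rest on few reads. Unclassified LTR elements (RLX) were lower, with a log2 difference of -0.56 (exact permutation adjusted p = 3.2e-04), and had 179 elements higher and 303 lower. The raw p of 4.9e-05 for L1 LINEs and for unclassified LTR elements is the smallest that this test can give. Helitrons (DHH) held a median of 56.6% of all TE counts, with 651 elements higher and 483 lower, and Gypsy elements (RLG) had 264 higher and 215 lower.

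The number of TEs called at each copy number was 1852 in 1B, 1803 in 2B, 1691 in 3B, 2144 in 4B, 1602 in 5B, 1985 in 6B and 1935 in 7B by edgeR. B-tagged TEs called higher numbered 92 in 1B, 114 in 2B and 128 in 7B. With spike-in scaling the share of TE calls that were higher was 76.2% in 1B (55.9% here), 87.5% in 4B (53.9%), 82.7% in 5B (54.9%) and 79.7% in 7B (53.6%), and less far from the main share in 2B with 61.9% (55.2%), 3B with 61.3% (55.1%) and 6B with 63.9% (54.1%). In 1B more TEs were lower than higher in some other settings. With only the 2 groups fitted, 555 were higher and 638 lower, and with no filter on low counts 792 and 858. Without Control replicates 2 and 4 and 1B replicate 3, 607 were higher and 630 lower. Other settings kept more higher than lower, such as DESeq2 with 928 and 844. The authors' deposited table has 683 TEs past its false discovery rate of 0.05 in 1B, 366 of them lower, and 1611 in 7B, 1311 of them higher. With dosage, 637 of 5074 TEs changed, 455 rising and 182 falling, and 123 of 227 B-tagged TEs rose and 6 fell. The Gypsy elements RLG00011Zm00004b00200 and RLG00011Zm00004b00287 rose by 0.56 ± 0.11 and 0.56 ± 0.10 log2 per copy (SE; edgeR adjusted p = 2.2e-04 and 5.7e-05), from 0.172 ± 0.344 and 0.569 ± 0.754 CPM in 1B (n = 4) to 9.55 ± 5.21 and 10.7 ± 3.34 in 7B (n = 3). The largest falls, in DHH00005Zm00004b03157 and RLG00007Zm00004b01320 (-0.81 and -0.73 log2 per copy, edgeR adjusted p = 0.0294 and 0.0101), rested on 1B replicate 3, since without it the slopes were -0.36 and -0.30 (edgeR adjusted p = 0.604 and 0.503). The share of dosage calls that rose was 71.4%, against 95.4% with spike-in scaling (393 calls), 89.0% with gene library scaling and 84.1% with no filter on low counts.

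Gene reads, taken as the FPKM sum times relative depth, were higher per ERCC read in carriers than in controls. The difference was 0.36 on the log2 scale (control mean -0.31 ± 0.37, n = 4, and carrier mean 0.05 ± 0.26, n = 24, with SD, exact permutation p = 0.0229, two-sided). The difference was 0.33 (exact p = 0.0656) without Control replicate 1, 0.26 (exact p = 0.131) without Control replicate 2 and 0.31 (exact p = 0.0834) without Control replicate 4. It was 0.30 (exact p = 0.0743) with the median of gene ratios. Among carriers it had no detected relation to copy number (r = -0.0171, permutation p = 0.938; rho = 0.0277, permutation p = 0.898). TE reads per gene read were lower in carriers, with a log2 difference of -0.36 (control mean 0.31 ± 0.40, n = 4; carrier mean -0.05 ± 0.21, n = 24; exact permutation p = 0.0193). That difference was -0.20 (exact p = 0.125) without Control replicate 4 and -0.11 (exact p = 0.107) without the 10 TEs with the most counts. Its relation to copy number gave r = -0.264 (permutation p = 0.228) and rho = -0.119 (permutation p = 0.578).

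Loci of the copper list were higher in carriers. These families are known to accumulate under copper shortage and to repress transcripts of copper proteins. All 4 measured loci rose with B presence, and 4 of 4 were called when adjusted over the list alone. Since all 4 had passed over all loci, the adjustment over the list could not fail. They were a locus matching the 3p arm of miR528 with 1 mismatch, not the 5p arm known as the regulator (147 ± 43.1 to 1979 ± 1040 CPM, log2 change 3.65 ± 0.48), 2 loci with the miR398 sequence (5528 ± 1867 to 13650 ± 4368, and 570 ± 247 to 1720 ± 723; log2 changes 1.28 ± 0.26 and 1.59 ± 0.37) and a miR408 locus (887 ± 509 to 2910 ± 1587; 1.68 ± 0.45), as mean ± SD in 4 controls and 24 carriers and log2 change ± SE (edgeR adjusted p = 2.1e-06, 7.1e-04, 0.00222 and 0.00516). The miR528 locus was above the highest control in 24 of 24 carriers, the miR398 loci in 23 each and the miR408 locus in 19. The miR408 call was lost without the 3 libraries with an unusual TE composition (log2 change 1.52, edgeR adjusted p = 0.0884).

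**Figure D4:**
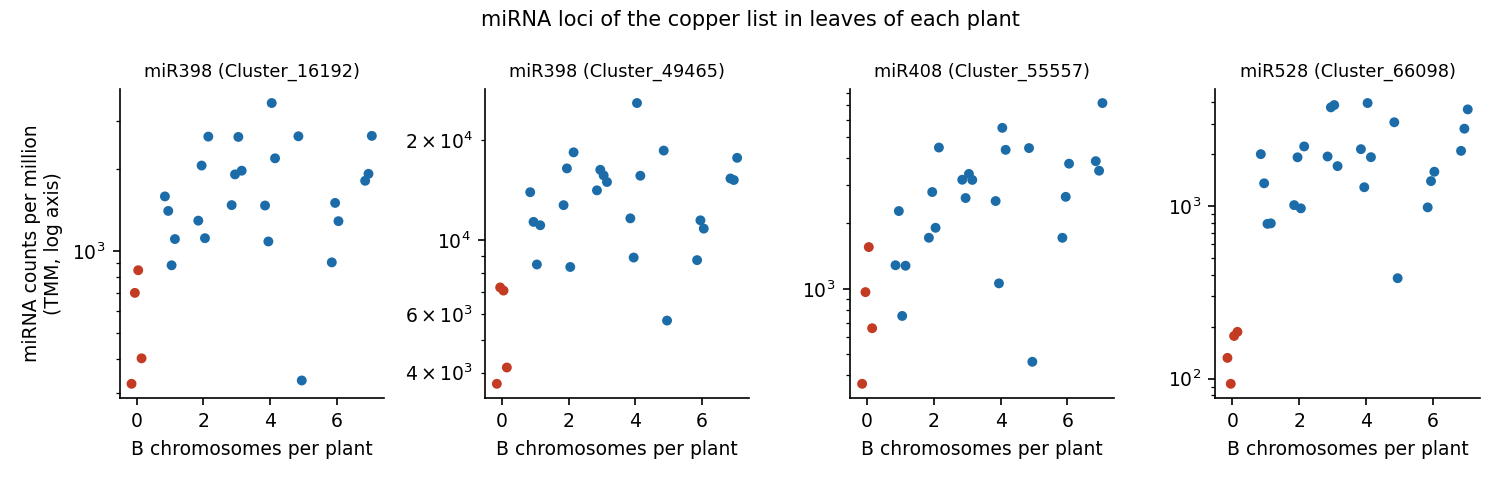
CPM (TMM-scaled, log axis) of the 4 miRNA loci of the copper list in each plant against B chromosomes per plant, with controls in red and carriers in blue. Every carrier lies above the controls at the miR528 locus, and 5B replicate 2 lies within the range of the controls at the miR398 and miR408 loci, as do 4 other carriers at miR408.

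Altogether 29 of 71 miRNA loci were called for B presence by edgeR, 12 higher and 17 lower. All scalings used were within miRNA reads. These made up 7.66% to 10.6% of small RNA reads in controls and 8.56% to 14.4% in carriers. Scaling by small RNA depth was not run, so the balance of higher and lower loci holds within miRNA reads only. The split was 13 and 11 with 7B replicate 1 as the TMM reference and 13 and 10 with no filter on low counts, and more loci were higher than lower with 6 of the 28 possible references. The calls of the 4 copper loci and of the miR171, miR1432, miR395 and miR167-3p loci below were kept with all 28. A miR171 locus with 1 mismatch rose from 241 ± 76.9 to 852 ± 238 CPM (log2 change 1.77 ± 0.24 SE, edgeR adjusted p = 2.1e-06; above every control in 24 of 24 carriers). Another miR171 locus with 1 mismatch fell from 321 ± 108.2 to 169 ± 69.1 (-0.97 ± 0.29, edgeR adjusted p = 0.0101), but by -0.56 without Control replicate 4 (edgeR adjusted p = 0.2238) and -0.54 without the 3 libraries with an unusual TE composition (0.381); the other 3 miR171 loci were not called. The miR395 locus of the sulfate list, a family induced by sulfate shortage, fell from 999 ± 297 to 486 ± 228 (log2 change -1.05 ± 0.22, edgeR adjusted p = 7.7e-04), and 1 of 1 was called over the list alone. With a list of 1 locus that second call uses the unadjusted p and could not fail. The miR1432 locus fell from 1985 ± 573 to 978 ± 214 (-1.04 ± 0.17, edgeR adjusted p = 2.7e-05). In the auxin list of 9 loci, 4 were called, also over the list alone. The miR167-3p locus was higher (372 to 811 CPM, 1.159 ± 0.28, edgeR adjusted p = 0.00242), while the more abundant miR167-5p locus was not (17150 to 14790 CPM, log2 change -0.22, edgeR adjusted p = 0.0998). The 3 miR393 loci were lower, a 5p locus, the strand known to target auxin receptor transcripts, by a log2 change of -0.56, and 2 loci with the same 3p sequence by -0.57 and -0.47 (edgeR adjusted p of at most 0.0251). These miR393 calls were weak: with each of the 28 libraries in turn as the TMM reference, 21 kept the 5p call and 16 and 14 the 3p calls. Of 28 runs with 1 library left out, 23 ended the 5p call and 24 and 25 the 3p calls, but 25 of those runs also had another reference library; with the reference kept, 2 of 27 ended the 5p call and 4 and 4 the 3p calls. Over the 28 runs the log2 changes stayed below 0, at -0.64 to -0.38, -0.66 to -0.41 and -0.57 to -0.31. With no filter on low counts the log2 changes were -0.42, -0.43 and -0.33 (edgeR adjusted p = 0.1462, 0.1499 and 0.1996). In the leaf development list of 14 loci, 4 of the 8 miR166 loci were higher by 0.26 to 0.31 and 1 of the 4 miR396 loci was lower (-0.51); over the list alone 5 were called. The 4 miR166 loci called share their sequence with 3 that were not called, and the most abundant of these 7 stood at 336200 ± 36300 CPM in controls and 345400 ± 47650 in carriers (log2 change 0.05, edgeR adjusted p = 0.738). Without Control replicate 3, 3 of the 4 miR166 calls were lost (edgeR adjusted p of at most 0.0652), while their log2 changes were 0.26, 0.26 and 0.26 against 0.30, 0.26 and 0.27. With the TMM reference kept, 26, 25, 24 and 24 of 27 runs kept the 4 miR166 calls. Each loss came without a control plant, namely Control replicate 2, 3 or 4. The miR399 locus of the phosphate list was lower (-0.91 ± 0.30, edgeR adjusted p = 0.0183) and the miR169 locus of the nitrogen list was higher (0.61 ± 0.18, edgeR adjusted p = 0.0101), each 1 call over its list alone too. The nitrogen list also has 1 locus, so its call over the list alone could not fail. None of the 6 phase change loci or 3 silencing feedback loci was called, by either adjustment, and the phase change median was 0.06. Without Control replicate 4, 19 loci were called, 12 higher and 7 lower, and the miR396 change was -0.15 (edgeR adjusted p = 0.520); 9 of the 28 runs ended the miR396 call and 5 the miR399 call, against 1 and 2 of 27 with the TMM reference kept, and the changes ranged from -0.62 to -0.15 and from -1.07 to -0.66. Without the 3 libraries with an unusual TE composition, 14 loci were called, 4 higher and 10 lower, with 2 controls left. Among the calls lost, log2 changes stayed near the values above for miR167-3p (1.01, edgeR adjusted p = 0.0874) and miR169 (0.53, 0.167), were larger for miR393 (-0.73, -0.69 and -0.63; 0.0511 to 0.0954) and were smaller for miR166 (0.13 to 0.21), miR396 (-0.20) and miR399 (-0.59).

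At each copy number fewer miRNA loci were called by edgeR: 12 in 1B, 12 in 2B, 12 in 3B, 16 in 4B, 9 in 5B, 13 in 6B and 17 in 7B. The miR528 locus ranked first among loci that rose at every copy number, with log2 changes of 3.05 in 1B, 4.24 in 3B and 4.24 in 7B (edgeR adjusted p = 1.9e-04, 1.5e-06 and 2.5e-06). In 5B its change was 3.54, and 1.54 without 5B replicate 1 (edgeR adjusted p = 0.283). The miR395 locus fell by 1.43 in 1B and by 1.58 in 3B (edgeR adjusted p = 0.0030 and 8.9e-04), while its mean was 882 ± 343 CPM in 6B (n = 3) against 999 ± 297 in controls (n = 4). In 2B it fell by 1.06 (edgeR adjusted p = 0.0196), a call lost without any of several single libraries, with changes of -0.92 (without Control replicate 4) to -0.77 (without 4B replicate 1) and an edgeR adjusted p of at most 0.1095. The balance of higher and lower calls was not stable. In 1B, 4 were higher and 8 lower, against 8 and 4 with relative log expression factors, 10 and 6 with DESeq2, 8 and 4 with no filter on low counts and 13 and 4 with 7B replicate 1 as the TMM reference. In the same order, 2B had 7 and 5 against 9 and 2, 10 and 4, 11 and 1, and 11 and 2, and 4B had 8 and 8 against 11 and 7, 13 and 8, 12 and 7, and 13 and 7. In 5B, 4 and 5 became 9 and 7 with DESeq2, 10 and 3 with no filter, 6 and 4 without TMM and 12 and 3 with that reference. In 3B, 7 and 5 became 7 and 3 with that reference, and in 7B 11 and 6 became 12 and 2 with no filter. The 5B count moved between 3 (without 5B replicate 1) and 17 (without 1B replicate 1) when single libraries were left out, and 19 libraries moved it by over 1.5 times. The 2B count was 6 without Control replicate 4 or 2B replicate 4 and 19 without 4B replicate 1, and without 1B replicate 2 the counts were 26 in 6B and 28 in 7B. Most of these runs also had another TMM reference, and the reference alone moved the count between 6 and 18 in 5B, 9 and 19 in 2B, 10 and 22 in 6B and 13 and 30 in 7B. The authors' deposited table has 11 miRNA loci past its false discovery rate of 0.05 in 1B, all 11 higher, and 15 in 7B, 14 of them higher.

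With B dosage, 0 of 70 miRNA loci passed the edgeR test, and 14 had an unadjusted p under 0.05; DESeq2 called 2. Adjusted over the list alone, 2 phase change loci, 1 phosphate locus, 1 sulfate locus and 1 silencing feedback locus were called. The sulfate list has 1 locus, so its p is unadjusted, and the phosphate list has 2. No adjustment was made over the lists, so these calls are weak. The largest slope in the copper list was that of miR408, at 0.18 ± 0.07 log2 per copy (SE; edgeR adjusted p = 0.132). Without 3B replicate 1, 5 loci were called, without 3B replicate 4 it was 2 and without 5B replicate 2 it was 2.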

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

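The test of a change that grows with each added B chromosome, the count of B-annotated genes lower in carriers and the slopes of the fallen genes in other settings were chosen after those results were seen; the other tests were set before.

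In 55 checks of 1 library against the rest of its group, 3 libraries lay far from the others, and about 1 group in 20 does so by chance. The small RNA depth of 1B replicate 4 was 600804 reads, against 849870 to 890236 in the other 1B plants. On the first principal component of A-chromosome genes, 2B replicate 4 lay at 18.1, against 10.8 to 11.2 in the other 2B plants. In 1B replicate 3, 31.4% of TE counts came from the top element, against 5.81% to 9.30% in the other 1B plants.

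The levels of many A-chromosome genes differed between controls and every carrier group. A change that grows with each added copy was argued against as the main source. The ratio of median changes at 7 copies and at 1 copy was 1.09. It was 1.07 with genes picked against Control replicates 1 and 2 and measured against Control replicates 3 and 4. The same carriers entered both steps. That most called genes lie in a few chromosome segments that differ between stocks was argued against. Only 2.95% of called genes lay in enriched windows. The windows cannot show whether such segments change genes that lie elsewhere, so that remains open. A stock, growth or harvest difference between controls and all carriers and an effect of the first B chromosome cannot be told apart, because 0 of the copy-number groups hold plants of both code series. A candidate explanation of either kind has to give a median change that is alike at 1 and at 7 copies. That does not hold for every gene, since 613 A-chromosome genes changed with dosage among carriers. A constant difference would also keep the ratio near 1 if a smaller part grew with copies.

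B-annotated genes with expression in controls were also weighed. Reads shared with A-chromosome copies at a constant level remain an explanation for most of the 92 genes, since the carriers' line extrapolated to 0 copies met the control mean within a median absolute log2 difference of 0.35, and 12 genes were off by more than 1. For the 15 such genes called lower in carriers, a constant A copy was argued against. Shared reads with A copies that themselves differ between controls and carriers remain possible. The difference was 1.06 times the median absolute change of A-chromosome genes, which was 0.33. This is the same 0.35 divided by a fixed value, so it adds no evidence of its own. It cannot tell constant from differing A copies. No biological explanation was tested, because sequence similarity of the copies was not analysed here.

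For A-chromosome genes that changed with dosage, reads of B transcripts assigned to A copies and a dose response of the A genes cannot be told apart for the 395 genes that rose. Their median step from control to 1 copy was 1.09 times the gain per copy, but the quartiles were -0.347 and 3.33 and 114 genes stepped down, so the median decides nothing. Added B reads alone give no step down, and the difference between controls and carriers enters each step. For the genes that fell the assignment of reads was argued against, since 218 fell and the highest count over random reassignments of copy numbers among carriers was 1. Fewer passed without 1B replicate 1 (92, with a highest random count of 0) and with spike-in scaling (11, with 1). Spike-in scaling moves all slopes nearly alike, by 0.0015 per copy. The median slope of the 218 genes, -0.0807 against -0.0828, was therefore fixed in advance and adds no support. Their standard errors grew 1.598-fold, and 7 stayed called. Without 1B replicate 1 the median slope was -0.0751, and 88 stayed called. A response of A-chromosome genes to B dosage is a hypothesis for the genes that fell.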

How the results depend on the processing

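The pseudocounts, the 1 FPKM filter, quantile normalization, TMM on FPKM, the other limit for B-specific genes, the TMM reference library and the removal of Control replicates 2 and 4 with 1B replicate 3 were chosen after the data were seen; the other alternatives were planned. Of 1094 recomputed comparison results, 1031 stayed (counts within 1.5 times, whatever their direction; other values with the same direction and side of the threshold), 57 counts moved by over 1.5 times and 6 lost their call. The majority direction was not stable for counts: in 134 of 978 recomputed counts (88 of miRNAs, 31 of TEs and 15 of genes) the majority of the calls lay on the other side, 101 of them with 1 library left out. For gene presence, 5697 higher and 5817 lower became 4163 and 3611 without the 3 libraries and 5949 and 5515 with TMM on FPKM. Of 4663 recomputed values of named features and lists, 4420 were kept, 243 lost their call and 0 reversed. Most of these features were picked for large changes, and outside dosage for the same direction in every copy number. The lack of reversals therefore adds little support. A feature that was no longer tested in a setting was left out of this tally. Spike-in scaling gave 5728 genes in 1B, 3981 in 2B, 3937 in 3B, 4289 in 5B, 4431 in 6B, 5205 in 7B and 264 for dosage, and 1176 TEs in 2B, 1271 in 6B and 393 for dosage; the shift it adds to all genes differs between groups, from 0.10 in 6B to 0.48 in 4B. Dosage over all 28 libraries gave 6976 genes (3707 rose, 3269 fell), 1530 TEs (660 rose, 870 fell) and 13 miRNAs, since it takes in the difference between controls and carriers. TEs numbered 4645 for presence with no low filter and 1193 in 1B with only the 2 groups fitted. For miRNAs, DESeq2 gave 16 in 5B and 2 for dosage, no TMM gave 3 for dosage, and 7B replicate 1 as the TMM reference gave 15 in 5B. Without the 3 libraries, 1B had 5550 genes, and miRNA calls numbered 14 for presence, 5 in 1B, 6 in 2B, 7 in 4B, 4 in 5B, 2 in 6B and 4 in 7B, with fewer controls. Gene reads per ERCC read gave 0.30 with the median of gene ratios, and TE reads per gene read gave -0.11 without the 10 TEs with the most counts. The cause of the other moves was not tested.

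With single libraries left out, counts ranged from 457 to 1113 for gene dosage and from 4851 to 7691 for genes in 5B (where 1 plant left is assumed to vary like other groups). miRNA counts ranged from 19 to 31 for presence, 6 to 19 in 2B, 3 to 17 in 5B, 10 to 26 in 6B, 13 to 28 in 7B and 0 to 5 for dosage. These miRNA ranges mix 2 things: in 25 of 28 runs TMM took another reference library than 3B replicate 2. With that reference kept, counts ranged from 17 (without Control replicate 4) to 30 for presence, from 5 (without 2B replicate 4) to 17 in 2B, from 5 (without 5B replicate 1) to 16 in 5B, from 6 (without 6B replicate 3) to 18 in 6B and from 8 (without 7B replicate 1) to 23 in 7B. With each library as the reference, presence gave 22 to 31 loci. For TEs 14 of 28 runs had another reference, and with the reference alone changed presence gave 2407 to 2444 TEs, with more higher than lower for 17 of 28. Gene reads per ERCC read ranged from 0.26 to 0.54 and TE reads per gene read from -0.47 to -0.20. Of the 4 copper loci, at least 3 stayed called in each of 36 settings (3 without the 3 libraries), and B-specific genes that rose numbered 82 to 102.

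The replicate number does not pair the plants: over 87 same-number pairs the correlation of deviations had a median of 0.0022 for genes (lowest -0.175, 9 over 0.1), -0.00672 for TEs (lowest -0.332, 11 over 0.1) and 0.0273 for miRNAs (lowest -0.500, 31 over 0.1), and 8, 3 and 9 of 28 libraries correlated best with their own number. As a block it gave 11365 genes for presence, 668 genes for dosage, 2385 TEs and 28 miRNAs for presence, and all 27 counts stayed within 1.5 times. DESeq2 and relative log expression factors were not run for genes because they need counts, and the gene list tests were not run because no identifier had a name. In the simulation with a fixed spread, gene changes of 1.5-fold were recovered for 2.99% of genes in 1B and 16.4% for presence.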

Other observations

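The counts of genes absent from either set of plants and the look at single plants and elements were chosen after the results were seen; the regroupings of plants were planned.

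Some A-chromosome genes were present in all plants of 1 kind and listed at 0 in the other. Of 40306 A-chromosome genes, 11 were at 0 in all controls and at 1 FPKM or more in each of the 24 carriers, and 4 were at 0 in all carriers and at 1 FPKM or more in each control. They lay on several chromosomes, with 3 of the 11 on chromosome 4. For B-annotated genes, 21 were at 0 in controls and at 1 FPKM or more in each carrier.

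The plant 5B replicate 2 had the lowest level of all carriers at each of the 4 copper loci. Its miR408 locus was at 462 CPM against 4443 in 5B replicate 1, but 4 other carriers also lay below the highest control of 1557 CPM there: 1B replicate 3 at 751, 4B replicate 2 at 1060, 1B replicate 4 at 1278 and 1B replicate 1 at 1284. Its miR398 loci were at 334 and 5734 against 2634 and 18629, and it was the only carrier within the range of the controls at these. The miR528 locus was at 382 CPM there, above the highest control at 187. In the TE table, the Helitron DHH00005Zm00004b03157 held 6.95% of the counts in 1B replicate 3, 7.85% in Control replicate 2 and 5.57% in Control replicate 4, and 0.0454% in Control replicate 1. In 4B replicate 2 it held 3.81%.

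Other groupings of the plants were fitted in the same way. For B presence, 1 of 100 regroupings (the real one included) gave as many genes as the real 11514, 2434 TEs and 29 miRNAs; the highest of the others gave 6154 genes, 1272 TEs and 7 miRNAs. For dosage, 1 of 100 gave as many as the real 767 genes and 637 TEs, with at most 1 gene and 2 TEs in the others. Chance can be excluded for these. With 0 miRNAs called for dosage, all 100 gave as many, and the highest gave 4. For the 3 enriched windows, 3 of 100 regroupings gave as many, with 6 at most; most of these regroupings called few genes, with a median of 0. For dosage the real grouping and the others gave 0 windows, so 100 of 100 gave as many.

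Against control, 1 of the 35 splits (the real one) gave as many calls as the real split at each copy number with 3 or 4 plants. This is the smallest share these splits can give, and it is below 0.05 for each comparison taken alone. The comparisons share the same 4 controls, and the shares were not adjusted for their number. The splits alone therefore do not exclude chance for each copy number. The nearest other split was that of miRNAs in 6B (13 calls against 11). The TMM reference alone moved that 6B count between 10 and 22. In genes the real counts and the highest others were 8653 and 2238 in 1B, 8258 and 8 in 2B, 8041 and 12 in 3B, 9598 and 10 in 4B, 9395 and 6266 in 6B, and 8797 and 5510 in 7B. In TEs they were 1852 and 154 in 1B, 1803 and 11 in 2B, 1691 and 2 in 3B, 2144 and 3 in 4B, 1985 and 1151 in 6B, and 1935 and 1072 in 7B. In miRNAs they were 12 and 3 in 1B, 12 and 3 in 2B, 12 and 6 in 3B, 16 and 7 in 4B, 13 and 11 in 6B, and 17 and 9 in 7B.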
